A study of Homo sapiens with 2 samples.

How the data were processed

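Total RNA from HSC-3 cells, a human squamous cell carcinoma line of the tongue, was measured on 2 one-colour microarrays, 1 for cells kept in monoculture and 1 for cells that shared medium, across porous inserts, with necrotic cells of the same line. Per the file headers, the arrays were labelled with Cy3, scanned and read with Agilent Feature Extraction, version 10.7.1.1, under the protocol GE1_107_Sep09, and the probe coordinates are those of hg19. The submitters' processing notes also name Agilent Feature Extraction. Both arrays lay on the same slide and were scanned in the same scan, so neither separates the groups. Per the file headers, the intensity analysed here (the processed signal) was background-subtracted and detrended within each array, and it was not normalised between arrays. The authors' deposited table of intensities was set against the scanner values: it equalled the processed signal for all 57901 probes printed once (within 1e-05 of the value) and the geometric mean of the spots for all 300 probes printed 10 times (within 1e-03).

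Each array held 60901 gene spots, which belong to 58201 probes. Control spots were left out, and so were spots that Feature Extraction marked as outliers, except where a probe had no other spot, in which case the probe was left out (3 probes on the co-culture array and 0 on the monoculture array). No gene spot was saturated. Repeated spots of a probe were averaged on the log2 scale. Of the probes, 41.7% were well above background on the monoculture array and 42.9% on the co-culture array, by the scanner's own flag. Since both shares were under 50%, each array was scaled by subtracting, from its log2 signals, the 75th percentile over the probes well above background on both arrays. That percentile was a signal of 1654 on the monoculture array and 2166 on the co-culture array. All differences are therefore relative to it and say nothing of a change in the total amount of RNA.

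A gene took the probe with the highest mean signal, among probes well above background on at least 1 array. Where a probe was well above background on 1 array only, the difference is a bound: the brighter signal was set against the higher of the dim probe's own signal and the lowest signal that was well above background on the dim array, and it is written as at least N-fold. Gene names were updated through a RefSeq gene table on GRCh38, used only for names. Of the 58201 probes, 34966 were matched (31104 by transcript accession, 3366 by current symbol and 496 by older symbol), and the names of the array design were kept for the other 23235. Coordinates are those of the array files on hg19, and no annotation of exons or untranslated regions was used.

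With 1 array per group there was no replicate, so no statistical test was made and no p-value is given. The 2 groups were compared by the log2 difference, co-culture minus monoculture, and genes were counted at 2-fold or more. The number of arrays limits the precision. The error that could be estimated is technical: the median SD of the log2 difference over repeated spots was 0.05 (284 probes). Feature Extraction's error model gives a median SE of 0.20 for a log2 difference. That SE is a model value and not a spread measured on these arrays, as bright genes all had the same 0.20. Neither the SD nor the SE covers labelling, RNA preparation or culture. Before the data were examined, 42 gene lists were fixed, together with the comparisons, the alternatives and the rule for the genes that are named. For each list with at least 5 measured members, the median log2 difference was placed among 10000 random lists of protein-coding genes of the same size, matched on mean signal in 20 bins. A list is said to stand apart in the upper or lower 2.5% of these, as a description of these 2 arrays. By the rule for named genes, the text names the 10 genes with the largest difference each way among those well above background on both arrays, with the brighter signal at or above the median. It also names the 4 with the largest bound each way, up to 4 members of each list that stands apart and 2 of each other list. Of the cytokine, matrix protease and mesenchymal lists it names 6, except that 1 gene of the mesenchymal list is left out. Genes named outside this rule are said to be so.

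The counts and list percentiles were tested on 20 simulated pairs of arrays that carried the measured spot noise for this comparison (19192 genes), each with 200 changed genes that were above background on both arrays. Of the planted genes, 1332 of 1340 with a 3-fold change and 1319 of 1320 with a 6-fold change were counted at 2-fold, and so were 14 of 1340 with a 1.5-fold change. All 20 lists of 20 genes planted with a log2 shift of 0.5 fell in the upper 2.5%, and 2 of 20 lists without a shift fell in either tail. The alternatives were normexp background correction (offset 50), quantile and cyclic loess normalisation, median centring, the percentile over all probes, no filter on dim probes, probes above background on both arrays only, the median of a gene's probes, the authors' table, random lists not matched on signal, and thresholds of 1.5-fold and 4-fold. After the data were seen, scaling on the spike-in controls, a restriction to bright genes and the removal of local patches of spots were added. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1 were used.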

Results

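Gene expression was measured in HSC-3 cells, an established line of human oral squamous cell carcinoma, after 16 h in monoculture or in indirect co-culture with necrotic cells of the same line. The necrotic cells had been killed by freezing in liquid nitrogen and thawing, and they were kept in inserts with pores of 1 µm at 2 necrotic cells per viable cell, so that soluble contents could reach the viable cells without contact between cells. The comparison asks which transcripts of the viable cells differed after exposure to what dead cells release. No insert is recorded for the monoculture. If it had none, an effect of the insert cannot be told apart from that of the necrotic cells. Each group had 1 culture and 1 one-colour array, so no difference below has a replicate check or a test, and each describes these 2 arrays. Of the 58201 probes, 24290 were well above background in the monoculture and 24955 in the co-culture. Over the 23612 probes above background on both, the log2 signals correlated with r = 0.987 across probes, which are not independent replicates. In all, 19192 genes were measured, of which 17739 were above background on both arrays, 988 in the co-culture only and 465 in the monoculture only.

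Among genes well above background on both arrays, with the brighter signal at or above the median, the largest higher difference was 17.9-fold. That was ASB2, a substrate adaptor of a ubiquitin ligase (signal 27.3 in the monoculture, near the lowest of 18.4 counted there as well above background, and 640 in the co-culture, log2 difference 4.16, error-model SE 0.30, probe on chromosome 14, 94400601 to 94400660, hg19). It was followed by SAA2, which encodes an acute-phase serum amyloid A protein (12.5-fold; chromosome 11, 18266791 to 18266850), ANGPTL4, a secreted inhibitor of lipoprotein lipase (log2 difference 3.42, signal 115 in the monoculture and 1612 in the co-culture; chromosome 19, 8439197 to 8439256), and CXCL8, the neutrophil chemoattractant interleukin-8 (9.40-fold; chromosome 4, 74609265 to 74609324). SAA1, S100A9, the EGFR ligand gene HBEGF, the steroid dehydrogenase gene HSD17B2, the complement gene CFB and the gelatinase gene MMP9 were 7.47-fold, 6.39-fold, 5.59-fold, 5.25-fold, 5.12-fold and 4.95-fold higher. SAA1 and SAA2 are close paralogs, and the share of signal that each probe takes from the other transcript was not measured.

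KRT1, a keratin of differentiating epidermis, showed the largest lower difference among genes chosen in the same way, at 29.5-fold (signal 8616 in the monoculture and 383 in the co-culture, log2 difference -4.88, error-model SE 0.20, chromosome 12, 53068520 to 53068579). LMO1, a transcriptional cofactor, was 19.8-fold lower (chromosome 11, 8245921 to 8245980), CHGA, which encodes chromogranin A, 10.5-fold (chromosome 14, 93401545 to 93401604), and EDN2, which encodes endothelin 2, 10.5-fold (chromosome 1, 41944456 to 41944515). DHRS9, a retinol dehydrogenase gene, the stromelysin gene MMP10, the keratin gene KRT16, the receptor gene NOTCH3, TENT5B and IGFBP3, which encodes an insulin-like growth factor binding protein, were 7.34-fold, 7.15-fold, 6.81-fold, 6.64-fold, 6.22-fold and 5.82-fold lower.

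Among genes above background on 1 array only, the largest bounds in the co-culture belonged to KCNA2, a potassium channel gene (at least 1391-fold), CSF3, the gene of granulocyte colony-stimulating factor (at least 20.9-fold), and the sphingosine-1-phosphate phosphatase gene SGPP2 (at least 14.6-fold). Both probes of CSF3 and both of SGPP2 were above background in the co-culture only, whereas the KCNA2 value came from 1 spot, and the other KCNA2 probe was not well above background on either array. The next in size was a probe named MIR146A in the array design. Whether its coordinates fall in the microRNA was not checked, so no value is given. The largest bounds in the monoculture belonged to PROX2 (at least 41.2-fold), TSL (at least 22.4-fold), the epidermal transcription factor gene ZNF750 (at least 15.9-fold) and RDH10-AS1 (at least 10.5-fold). The PROX2, TSL and RDH10-AS1 spots lay close together in a part of the monoculture array where 9 of 16, 10 of 15 and 8 of 18 neighbouring spots were also 2-fold or more brighter there. The second probes of PROX2 and TSL were not well above background on either array.

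At 2-fold or more, 331 genes were higher in the co-culture (79 of them by a bound) and 704 were lower (170 by a bound), of which 237 and 406 encode proteins. Under other scalings the split was 426 to 511 (quantile), 434 to 515 (cyclic loess) and 428 to 528 (75th percentile over all probes), and scaling on spike-in controls gave 2471 to 153. The excess of lower genes was thus smaller under the other scalings and turned into an excess of higher genes under spike-in scaling. In 20 simulated pairs that differed by spot noise alone, at most 60 genes were higher and at most 42 lower. The simulated noise leaves out labelling, RNA preparation and culture. These counts therefore do not show how many genes would differ between cultures treated alike. Of the 40 gene lists with enough measured members, 16 stood apart as higher and 6 as lower, where lists of genes drawn at random would give 1 in each direction. Some lists share members, and genes of a list can vary together between cultures. The number expected from cultures treated alike is therefore not known.

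**Figure D1:**
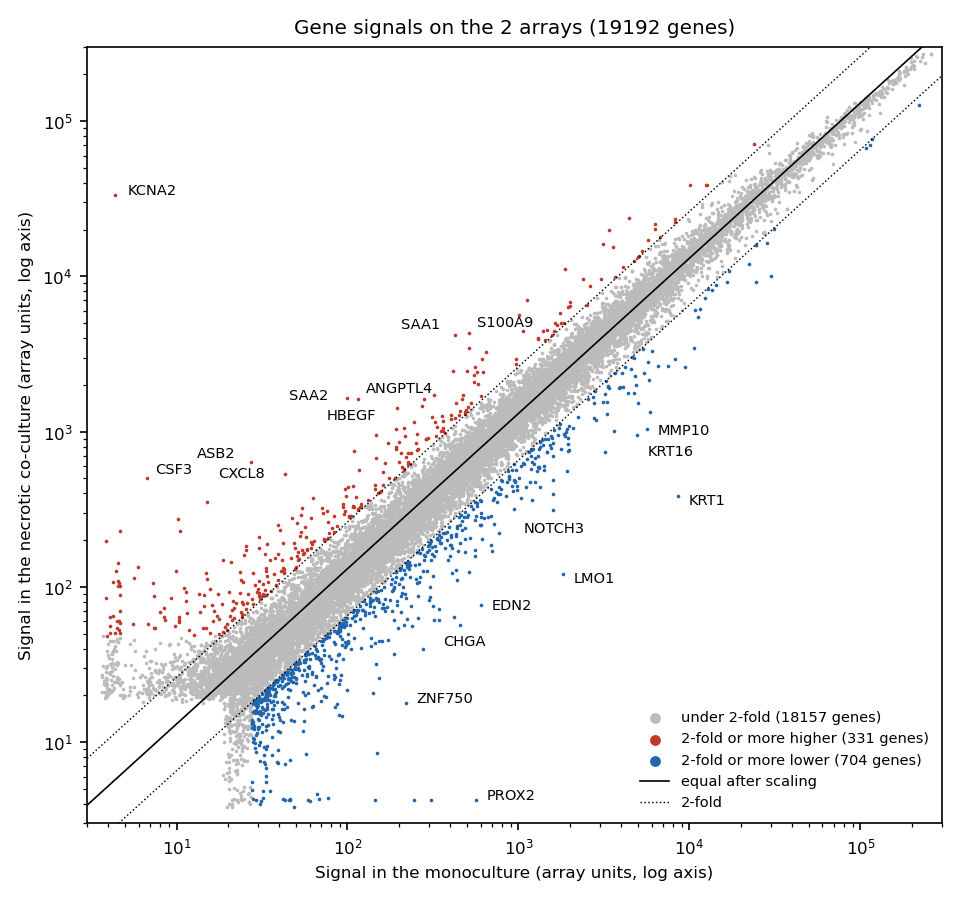
Signal of each gene in the monoculture (horizontal, array units, log axis) against its signal in the necrotic co-culture (vertical, array units, log axis) for 19192 genes, with the line of equal signal after scaling and dotted lines at 2-fold. The 331 genes counted as higher are red and the 704 counted as lower are blue (genes above background on 1 array are counted by their bound), and KCNA2, CSF3, SAA2 and KRT1 lie among those farthest from the line.

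Cytokine and chemokine genes that respond to NF-kB and interleukin-1 were higher in the co-culture as a group. Of the 22 measured, 17 were 2-fold or more higher and 0 were 2-fold or more lower, with a median log2 difference of 1.73, above all 10000 random lists. CSF3 and CXCL8 belong to it, as do CCL20, a chemoattractant of lymphocytes and dendritic cells (at least 9.53-fold), CSF2, the gene of granulocyte-macrophage colony-stimulating factor (at least 8.16-fold), and the neutrophil chemokine genes CXCL2 (4.79-fold) and CXCL3 (4.17-fold). The NF-kB feedback and target genes showed the same direction: 13 of 22 were 2-fold or more higher and 0 lower, with a median of 1.19, above all random lists. Besides SAA1 and SAA2, its largest members were LCN2, which encodes the siderophore-binding lipocalin 2 (4.55-fold), and SOD2, the mitochondrial superoxide dismutase gene (4.10-fold).

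**Figure D2:**
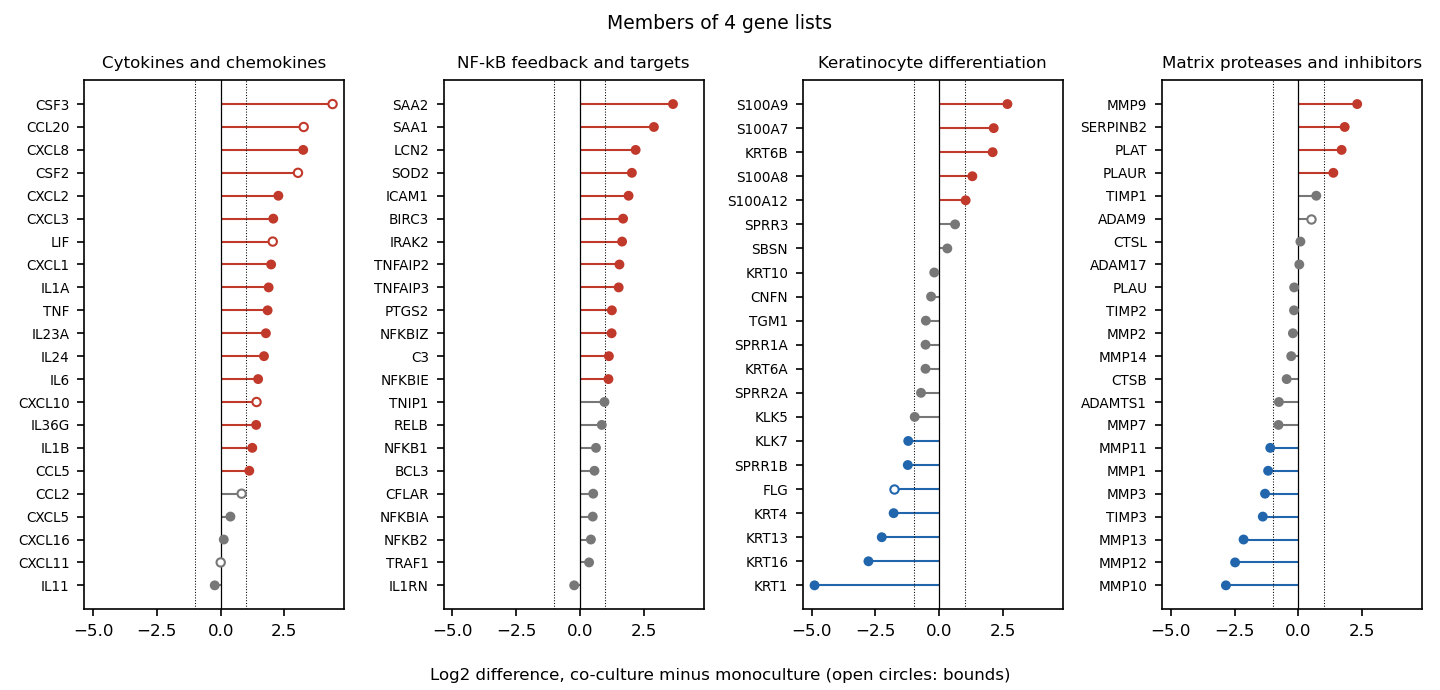
Log2 difference, co-culture minus monoculture, of the measured members of 4 gene lists (1 protease or inhibitor gene is not drawn), with filled circles for differences, open circles for bounds and dotted lines at 2-fold. Of the 22 cytokine and chemokine genes 17 lie at or beyond 2-fold on the higher side, while the keratinocyte differentiation genes (5 higher, 7 lower) and the matrix proteases and inhibitors (4 higher, 7 lower) lie on both sides. FLG was measured in a local patch of spots.

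Interferon-responsive genes were higher by less. Of 25 measured, 24 had a difference above 0 and 2 reached 2-fold, with a median of 0.49, above all random lists. The 2 were OASL (2.58-fold) and the ubiquitin ligase gene HERC5 (at least 2.47-fold). The RNA sensor gene RIGI was 1.97-fold and MX2 1.84-fold higher, but their probes disagreed and ranged from -0.12 to 0.98 and from -0.35 to 0.88 in log2. Antigen presentation genes had a median of 0.17 (98.87th percentile) and none of 16 reached 2-fold. HLA-DRA and CIITA, the regulator of class II genes, were 1.92-fold and 1.76-fold higher, and the peptide transporter gene TAP1 and HLA-C 1.44-fold and 1.25-fold. This list left the upper 2.5% against random lists not matched on signal (97.08th percentile). Receptors for released cell contents, such as those for nucleotides and bacterial or nuclear products, had a median of 0.28 (99.96th percentile), with 3 of 18 at 2-fold or more: the Toll-like receptor gene TLR4 (at least 5.24-fold), the nucleotide receptor gene P2RY6 (3.71-fold) and the DNA-response adaptor gene STING1 (2.02-fold). TLR2 was 1.86-fold higher. The list's place was lost with normexp correction (94.53rd percentile), without a filter on dim probes (77.1st) and with probes above background on both arrays (95.8th). Among cell death genes (median 0.23, 99.67th percentile, 1 of 21 at 2-fold), the inflammasome gene NLRP3 was 3.57-fold higher, and the death receptor gene FAS, the necroptosis effector gene MLKL and TNFRSF10A were 1.85-fold, 1.71-fold and 1.69-fold higher.

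The EGFR family list had a median of 0.50, above all random lists, with 3 of 10 members 2-fold or more higher and 0 that much lower. These 3 were the ligand genes HBEGF, EREG (3.85-fold) and AREG (2.28-fold). Of the 10 members, 7 were above 0. The receptor genes ERBB2 and ERBB3 and the ligand gene TGFA, named after their values were seen, were lower (log2 differences -0.37, -0.56 and -0.16). Another ligand gene, BTC, was above background in the co-culture only, with a log2 difference of at least 0.59. Immediate early and AP-1 genes were divided, with 5 of 22 at 2-fold or more higher and 2 lower and a median of 0.19 (99.32nd percentile). The feedback inhibitor genes SPRY4 (5.23-fold) and DUSP6 (3.06-fold), the AP-1 gene FOSL1 (4.10-fold) and IER3 (2.32-fold) had the largest higher values. The others at 2-fold, named after their values were seen, were SPRY2 (2.00-fold higher), EGR2 (4.33-fold lower) and FOSL2 (2.21-fold lower). This list's place was lost under quantile normalisation (97.42nd percentile) and with bright genes only (96.57th). All 27 DNA replication genes were above 0, with a median of 0.57, above all random lists, and 0 reached 2-fold. POLE2, CDT1, MCM6 and E2F1 were 1.80-fold, 1.69-fold, 1.66-fold and 1.58-fold higher. All 20 ribosome biogenesis genes were above 0 as well, with a median of 0.40, again above all random lists. They included NOP56 (1.72-fold), NOP16 (1.44-fold), PNO1 (1.39-fold) and GNL3 (1.38-fold).

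Several stress and metabolic lists stood apart as higher. Targets of the aryl hydrocarbon receptor had a median of 0.58 (99.99th percentile), and 2 of 8 reached 2-fold, the retinaldehyde dehydrogenase gene ALDH1A3 (4.51-fold) and CYP1A1 (2.46-fold), while CYP1B1 and TIPARP were 1.95-fold and 1.74-fold higher. All 9 measured metallothionein and zinc genes were above 0, with a median of 0.60, above all random lists, and the largest were MT1B (1.98-fold), MT1X (1.95-fold), MT1E (1.88-fold) and MT1A (1.65-fold). The metallothionein genes are close paralogs, so their values are not independent of one another where probes bind related transcripts. Genes of the ATF4 amino acid response had a median of 0.29 (99.99th percentile), with 3 of 23 at 2-fold or more higher and 1 lower. The 3 were STC2 (3.18-fold), GDF15 (2.40-fold) and CHAC1 (2.13-fold), and VLDLR was 1.83-fold higher, while the lower gene, named after its value was seen, was NUPR1 (2.63-fold). Endoplasmic reticulum chaperone genes had a median of 0.19 (99.21st percentile), with 0 of 18 at 2-fold, and included XBP1 (1.68-fold), MANF (1.39-fold), DNAJB11 (1.35-fold) and PDIA6 (1.31-fold). Hypoxia and HIF targets had a median of 0.18 (98.81st percentile), with 3 of 21 at 2-fold or more higher and 2 lower. The 3 were ANGPTL4, STC2 and CA12 (3.02-fold), and VEGFA was 1.62-fold higher, while the lower genes, named after their values were seen, were PFKFB4 (log2 difference -1.59) and ADM (2.14-fold). Glycolysis genes had a median of 0.13 (97.69th percentile), and 1 of 17 reached 2-fold, the lactate transporter gene SLC16A3 (2.06-fold), with HK2, GPI and LDHA at 1.38-fold, 1.22-fold and 1.22-fold. The hypoxia list lost its place without a filter on dim probes (94.8th percentile) and with bright genes only (78.6th), and the glycolysis list lost its place against random lists not matched on signal (93.0th) and, by a small margin, with the median of a gene's probes.

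**Figure D3:**
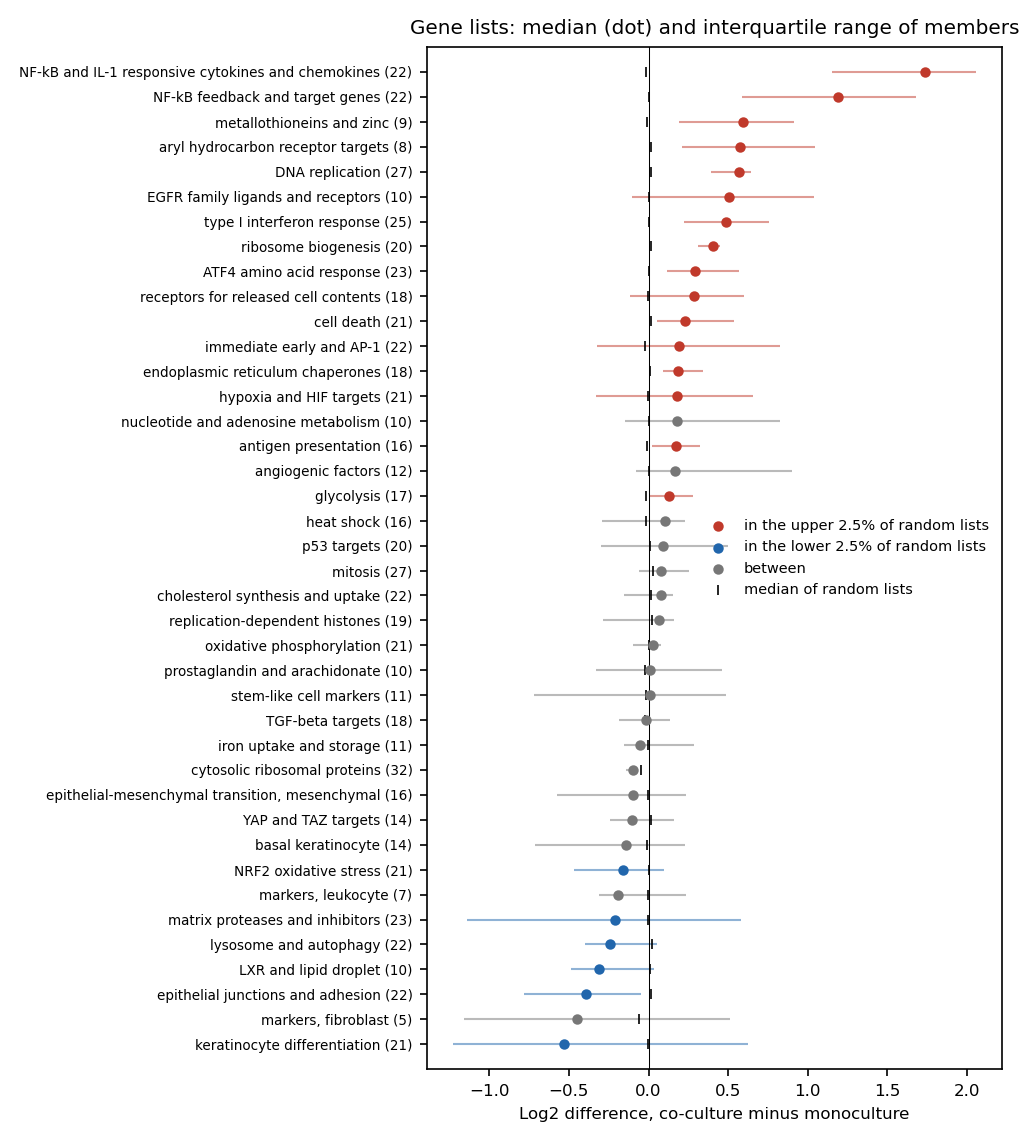
Median (dot) and interquartile range (line) of the log2 difference, co-culture minus monoculture, over the measured members (number in brackets) of 40 gene lists, with a tick at the median of 10000 random lists of the same size. The 16 lists in the upper 2.5% are red and led by the cytokine list at 1.73, and the 6 in the lower 2.5% are blue, with keratinocyte differentiation at -0.53, although all 6 of these medians lay above 0 on the spike-in scaling.

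Genes of keratinocyte differentiation were lower as a group relative to the 75th percentile, with a median of -0.53, below all 10000 random lists (0.11 on the spike-in scaling), but the members were divided. Of 21, 7 were 2-fold or more lower and 5 were 2-fold or more higher. The keratin genes KRT1, KRT16, KRT13 (4.75-fold) and KRT4 (3.44-fold) had the largest lower values. The 5 that were higher, named after their values were seen, were KRT6B and the calcium-binding protein genes S100A7, S100A8, S100A9 and S100A12. Of the 7 lower genes, FLG, also named after its value was seen, was measured in a local patch of spots. Genes of epithelial junctions and adhesion had a median of -0.39, also below all random lists (0.25 on the spike-in scaling), with 4 of 22 at 2-fold or more lower and 0 higher. These were the desmosomal genes DSC2 (3.95-fold), DSC3 (2.62-fold) and PKP1 (2.35-fold) and the transcription factor gene OVOL1 (3.05-fold).

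Matrix proteases and their inhibitors had a median of -0.21 (0.88th percentile; 0.43 on the spike-in scaling), with 7 of 23 at 2-fold or more lower and 4 higher. The metalloproteinase genes MMP10, MMP12 (5.57-fold) and MMP13 (4.42-fold) and the inhibitor gene TIMP3 (2.62-fold) were lower. MMP9, SERPINB2, an inhibitor of urokinase (3.53-fold), and PLAT, which encodes tissue plasminogen activator (3.24-fold), were higher, as was the urokinase receptor gene PLAUR (2.59-fold), named after its value was seen. The LXR and lipid droplet list (median -0.31, 0.24th percentile, 0 of 10 at 2-fold; 0.33 on the spike-in scaling) included ABCA1, MYLIP, SREBF1 and ACSL1 at 1.77-fold, 1.53-fold, 1.42-fold and 1.36-fold lower, and its place was lost with bright genes only (6.92nd percentile). Lysosome and autophagy genes (median -0.24, 0.01st percentile; 0.40 on the spike-in scaling) had 1 of 22 at 2-fold, GPNMB (2.37-fold lower), and ULK1, CTSD and GABARAPL1 were 1.88-fold, 1.49-fold and 1.48-fold lower. NRF2 targets (median -0.16, 1.01st percentile; 0.48 on the spike-in scaling) were led by the heme oxygenase gene HMOX1 (2.41-fold lower), followed by AKR1B10, GCLC and GPX2 at 1.81-fold, 1.54-fold and 1.53-fold lower, while ABCC3, named after its value was seen, was 2.36-fold higher. The NRF2 list's place was lost under quantile normalisation (12.45th percentile) and against random lists not matched on signal (3.10th).

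The other 18 lists with enough members did not stand apart, and on the spike-in scaling the medians of all 18 lay above 0. Mesenchymal genes of the epithelial-mesenchymal transition had a median of -0.10, with COL1A1 and SPARC at 2.24-fold and 2.21-fold lower, LOX and COL5A1 at 1.68-fold and 1.60-fold lower, and TWIST2 at 1.54-fold higher. Basal keratinocyte genes had a median of -0.14, with KRT15 and KRT5 at 2.29-fold and 2.00-fold lower. Medians were -0.01 for TGF-beta targets (ID3 3.30-fold and TGFB2 3.13-fold lower), -0.11 for YAP and TAZ targets (NT5E 2.06-fold higher, PTPN14 1.54-fold lower), 0.08 for cholesterol synthesis (SC5D 1.37-fold lower, IDI1 1.34-fold higher), 0.10 for heat shock (CRYAB 3.41-fold and HSPB1 2.09-fold lower, the latter with probes from -1.07 to -0.50 in log2), -0.06 for iron handling (LCN2 and HMOX1 as above) and 0.09 for p53 targets (PLK3 2.81-fold higher, GDF15 as above). Mitosis genes had a median of 0.08 (TTK and AURKB 1.30-fold higher each), replication-dependent histones 0.06 (H2AC6 1.88-fold lower, with probes from -0.91 to -0.03 in log2, H1-3 1.65-fold higher), cytosolic ribosomal proteins -0.10 (RPL23 1.19-fold and RPS6 1.18-fold lower) and oxidative phosphorylation genes 0.03 (UQCRC1 1.34-fold lower, SDHB 1.19-fold higher). The nucleotide and adenosine list had a median of 0.18 (NT5E as above, PNP 1.91-fold higher), angiogenic factors 0.17 (ANGPTL4 as above, PGF 4.58-fold higher), the prostaglandin list 0.01 (ALOX5 2.61-fold lower, PTGS2 2.38-fold higher) and markers of stem-like cells 0.01 (SOX2 4.53-fold lower, ALDH1A3 as above).

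The leukocyte and fibroblast marker lists did not stand apart either, with members on both sides of 0. Of 12 leukocyte markers, 10 had a probe, and of these 6 were above background in the monoculture and 7 in the co-culture, with a median difference of -0.19 over 7, of which CD14 was 2.08-fold and ITGAM 1.38-fold higher. Of 11 fibroblast markers, 5 were above background on each array (median -0.45), with DCN and COL1A1 at 2.35-fold and 2.24-fold lower. Of 10 endothelial markers, 2 and 3 were above background in the monoculture and the co-culture, and of 9 neural and melanocyte markers 3 on each array, which was too few to place these lists.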

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

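All tests of explanations in this part were chosen only after the result they bear on was seen. For these tests, CD79A, CSF1R, HES1, HEY1, NRARP, HES2 and HES4 are named outside the naming rule. The E1A spike-in controls, which the comparison does not use, were lower in the co-culture relative to the genes: all 7 with a signal of 50 or more had a log2 difference below 0 after gene scaling, with a median of -0.64 and a range from -0.69 to -0.33. Before scaling, their median difference was -0.25 while the genes' 75th percentile was 0.39 higher in the co-culture. The positions of the spots also carried a signal. For 95 of the 60901 gene spots, the median over the spots within 25 pixels differed between the arrays by 0.5 or more in log2 after the difference at the same signal was removed, against at most 12 in 20 shufflings of the positions.

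The inflammatory lists were the pattern farthest from random lists. A difference between the arrays that follows signal is argued against as the whole cause, since after cyclic loess, which removes such a trend, the lower of the 2 list medians was 1.25, against 1.19 before. RNA from leukocytes has no source in the design, since the viable and the necrotic cells were of the same line. The median over 7 leukocyte markers was -0.19, with an upper quartile of 0.23. On the spike-in scaling the marker median was 0.41, against 1.83 for the lower of the list medians. These markers are a weak test, because 6 of the 10 with a probe were above background in the monoculture too. The most abundant were CD79A (signal 1878 in the monoculture and 1860 in the co-culture), CD14 (1426 and 3877) and CSF1R (441 and 429), of which CD14 alone was 2-fold or more higher. Variation from culture to culture stays open and cannot be told apart from the treatment, since each group had 1 culture. The release of cell contents by the necrotic cells, which the design names, stays among the open explanations as untested.

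Lower expression of differentiation genes beside higher S100A8 and S100A9 was the second pattern. For the keratinocyte differentiation list, the median log2 difference was -0.53, and after cyclic loess it was -0.54, which argues against a trend with signal as the whole cause. A separate list of transcription factors of keratinocyte differentiation was written after the main results were seen. Over its 12 members that had not yet been named, the medians were -1.20 and -1.16. Local patches of the size sought here are argued against as well. Of the 21 measured keratinocyte differentiation genes, 20 remained without the probes in patches. The list's median was -0.53 without those probes, as with them (0.11 with them on the spike-in scaling). A weaker mark could escape the criterion, which did not take in RDH10-AS1 (median of its neighbouring spots -0.34). Lower Notch signalling may contribute, as NOTCH3 was lower and 13 other Notch pathway genes had a median of -0.33 (0.36th percentile, and 0.31 on the spike-in scaling). Its direct target genes HES1, HEY1 and NRARP, however, had a median of 0.59. HES2 and HES4, which belong to the same family as HES1, had log2 differences of -1.37 (probes from -1.37 to -0.38) and -0.37. The tables do not decide. Variation from culture to culture is open here too.

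The third pattern was the set of genes seen on 1 array only. Of the 4 with the largest bounds in the monoculture, 3 (PROX2, TSL and RDH10-AS1) had 8 to 10 of their 15 to 18 neighbouring spots 2-fold or more brighter in the monoculture too, whereas the 135 other genes that the naming rule gives had at most 3 neighbours that differed so in their own direction. A local mark on that array is a candidate explanation for these 3, and ZNF750 is not among them. Of the 4 with the largest bounds in the co-culture, 0 had more than 3 neighbours of that kind, which argues against a patch for CSF3, SGPP2 and KCNA2. A mark on the single KCNA2 spot was not tested by its neighbours. The pixels of that spot had a coefficient of variation of 16.2%, and the scanner did not mark it as non-uniform.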

How the results depend on the processing

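Scaling on the spike-in controls, the restriction to bright genes and the removal of local patches were chosen after seeing the data. No paired analysis was possible because each group had 1 array, and for the same reason no replicate could be left out and no other split of the arrays exists. Against 331 higher and 704 lower genes, the counts moved by over 1.5 times with normexp correction (127 and 301), without a filter on dim probes (1070 and 3162), with spike-in scaling (2471 and 153), with bright genes only (135 and 226), at 1.5-fold (1065 and 2144) and at 4-fold (57 and 84). The filters and thresholds change how many genes can be counted, and the spike-in scaling moves the median gene by 0.64 in log2. The cause of the normexp difference was not tested. Under quantile normalisation, cyclic loess, median centring, the percentile over all probes (which moves the median gene by 0.10), probes above background on both arrays, the median of a gene's probes, the authors' table and removal of patches, counts stayed between 252 and 434 higher and between 511 and 704 lower, and the share of higher genes among those counted, 32.0%, was 45.5% with quantile normalisation, 45.7% with cyclic loess, 44.8% with the percentile over all probes and 94.2% with spike-in scaling. Of 13 alternatives, 4 (median centring, the percentile over all probes, spike-in scaling and the authors' table) shift all genes alike or use the same values, so a list's place among random lists was fixed or nearly so. Over the other 9, 11 of the 16 higher lists and 4 of the 6 lower lists kept their place in each, 5 and 2 lost it in at least 1, and 0 moved to the opposite tail, although the medians of all 6 lower lists lay above 0 on the spike-in scaling. Lists that stood apart only under an alternative were YAP and TAZ targets (quantile, bright genes), heat shock (normexp, quantile), the nucleotide list (bright genes), angiogenic factors (cyclic loess, no filter) and fibroblast markers (unmatched random lists). The restriction to bright genes gave no value for the prostaglandin list and for the leukocyte and fibroblast markers. Of 1666 recomputed differences of the 143 genes that the naming rule gives, 1456 lay within the error-model SE of the value given and 210 moved further. Median centring and the percentile over all probes shift all genes by less than that SE. The authors' table, bright genes only, probes above background on both arrays and removal of patches reuse the same probe values. Under all of these no value moved, largely by construction. Spike-in scaling, which shifts all genes alike, moved 136. Normexp moved 52, no filter on dim probes 11, the median of a gene's probes 10, quantile 1 and cyclic loess 0. In all, 14 changed sign, all of genes under 2-fold: 12 under spike-in scaling (among them SC5D, PTPN14 and CTSD), whose shift is too small to turn a 2-fold gene, and ITGAM and RPL23 with normexp and quantile. Signal over background limits the dim genes: repeated spots with a log2 signal under 5 had a median SD of 0.32 in the monoculture and 0.36 in the co-culture, against 0.04 at 11 or more.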

Other observations

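The lists in this part were written after the main results had been seen, and their tests were chosen then too, so their percentiles describe the lists and do not test them. The members named from them were chosen after their values were seen. Values are given without the members that an earlier list or the naming rule had already covered. Of 7 further genes that report ERK pathway output (without SPRY2, SPRY4 and DUSP6), 3 were 2-fold or more higher and 1 was lower, with a median log2 difference of 0.87. The transcription factor genes ETV4 and ETV5 were 3.18-fold and at least 3.02-fold higher, and the phosphatase gene DUSP4 2.45-fold, while the ephrin receptor gene EPHA4 was 3.92-fold lower. Complement and acute-phase genes, without CFB and C3, had a median of 0.48 over 11, with 1 at 2-fold, SERPINA3 (2.08-fold, with probes from 0.32 to 1.70 in log2). Interleukin receptor genes had a median of 0.40 over 18 (99.99th percentile) but went both ways, with IL13RA2 2.71-fold and IL4R 2.17-fold higher and IL6R 2.94-fold lower. Polyamine and nucleotide synthesis genes had a median of 0.38 over 13 (99.98th percentile), led by the ornithine decarboxylase gene ODC1 (2.10-fold). Amino acid transporter genes had a median of 0.23 over 8 (95.68th percentile; 98.73rd with the 4 that had been covered), with SLC43A1 2.48-fold higher and SLC1A4 and SLC7A8 lower (log2 differences -1.73 and -1.58).

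Of 11 further transcription factor genes of keratinocyte differentiation (without KLF4, OVOL1 and ZNF750), 8 were 2-fold or more lower and 0 higher, with a median of -1.25 (-0.61 on the spike-in scaling). These included MAF (5.69-fold), GRHL3 (5.53-fold), HOPX (2.60-fold), GATA3 (2.40-fold) and CEBPA (2.37-fold), while KLF4, left out of this count, had a log2 difference of 0.45. Wnt ligands and receptors had a median of -0.22 over 18 (0.60th percentile; 0.42 on the spike-in scaling), with WNT6, FZD10 and WNT4 3.72-fold, 3.16-fold and 2.73-fold lower. Glucocorticoid targets had a median of -0.40 over 6 (1.95th percentile; 0.24 on the spike-in scaling), but with the 3 that had been covered the percentile was 3.14. Retinoid genes had a median of -0.23 over 9 (3.42nd percentile; 1.01st with ALDH1A1, which had been covered; 0.40 on the spike-in scaling), and the 1 member at 2-fold, RARRES1, was 2.03-fold higher. BMP targets (median -0.47 over 6, 4.37th percentile, and 0.16 on the spike-in scaling; -0.01 and the 49.8th percentile with the 5 that had been covered) and immune checkpoint ligands (0.13 over 10, 88.5th percentile) did not stand apart.

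The replication genes stood apart and the mitosis genes did not. One hypothesis is that more cells were in the cycle in the co-culture, spread over its phases as in the monoculture, which would raise both. The median of the 27 mitosis genes was 0.078, below the 0.57 of the replication genes by more than the mitosis genes' interquartile range of 0.31, which argues against it as the whole cause. On the spike-in scaling the medians were 0.71 and 1.21, with the mitosis genes above 0 as well, so a part played by more cells in the cycle stays open. A shift within the cycle may also be involved and was not tested.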
